A study of Mus musculus with 24 samples.

How the data were processed

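Gene expression in liver was measured by RNA sequencing in 24 libraries, 12 from C57BL/6 mice that overexpressed L2d13 and 12 from wild-type mice. Per the labels, total RNA was extracted with TRIzol and sequenced on the BGISEQ-500 platform. The submitters' processing notes name HISAT, Bowtie2 and RSEM, without versions, and the build GRCm38.p5. The FPKM values were made by the authors and were used as deposited, with 2 decimals, for 18171 genes; no further normalization is stated. Read totals cannot be had from FPKM, so no depth per library is given. FPKM per fragment was compared between libraries from the steps between the values of 301 low genes. Of their 3444 values above 0, 79.2% lay within 0.2 of a whole number of steps. The step of a gene was taken from its own lowest values, which therefore tend to lie in that window. Other values can also lie in it by chance, so this share is no independent check of the measure. All 24 columns belonged to a sample (columns of no sample: 0), and no pair of libraries held identical values. Correlations between libraries ran from 0.909 to 0.992, with a median of 0.984 within groups and 0.971 between groups.

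Of the gene identifiers, 18040 matched a symbol of the RefSeq table and 131 did not. That table is of GRCm38.p6 and was used for names and for the order of neighbouring genes only. Exon coordinates, transcript sequences and transcript lengths came from the GENCODE M21 annotation of GRCm38. The share of fragments of a gene was taken as FPKM times length, with the median or the longest coding transcript of 17463 genes. Libraries were grouped by genotype and by the digit 2 or 4 in their sample names, which gave 4 groups of 6 libraries. The meaning of that digit is not given by the labels, and no claim rests on it.

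Genes with an FPKM of at least 1 in at least 6 libraries were kept, which left 10532. The log2 of FPKM + 1 was fitted with limma 3.58.1 in R 4.3.3 (statmod 1.5.0) with moderated variances that follow the mean. The genotype over both sets and the set over both genotypes came from a fit with additive terms for set and genotype. A fit with 1 mean per group gave the genotype within each set, the difference between these, and the set in wild-type livers alone. Over all 24 libraries the genotype over both sets equals the mean of the differences of the sets. In fits on unequal numbers of libraries it need not. The spread in the additive fit also takes in any difference between the genotype effects of the sets. All tests were two-sided. P-values were adjusted by the method of Benjamini and Hochberg within each contrast, and genes with an adjusted p under 0.05 are those called. Folds are 2 to the power of the log2 difference and so include the pseudocount of 1. Loxl2, Gm21451 and their sum were also tested by permutation of the labels within sets, exact within 1 set. Tables and plots were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

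Gene groups came from 50 lists, 35 of pathways with the lysyl oxidase family among them, 14 of cell types and 1 of sex-linked genes, fixed before the data were examined, as were the groups, the contrasts, the filter, the threshold, the rule for naming genes and the first group of other settings below. The 42 lists with at least 4 tested members were tested with camera at a preset correlation between genes of 0.01, and again with a correlation estimated from the data and with fry. Lists with fewer tested members, such as those of skeletal muscle and exocrine pancreas, were not tested.

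For the genotype over both sets the rule names, among the genes called with the same sign in both sets and a mean FPKM of at least 1 in the higher genotype, the 10 with the largest rise and the 10 with the largest fall. For the other contrasts it names the 5 largest of each. Predicted genes and clone names are passed over. The lysyl oxidases and the Y-linked genes are always given, while Xist was not analysed here. For a called list the 4 members with the smallest p are named, and for a list counted without a call 2. In 1 respect the rule was not followed: for the contrasts other than the genotype over both sets, members are given only for the lists with the smallest p and for markers of cell types, a choice made after the values were seen. Some genes that the rule names are not reported here, and counts of genes and list members still include them. No gene is named by rule for the sets in wild-type livers.

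The procedure was tested on simulated data, made from the spread within groups with 100 genes changed by a known fold. Of genes changed 2-fold, 96% were found over both sets, 87% in set 2, 88% in set 4, 67% in the difference between sets and 97% between the sets. Of genes changed 1.5-fold these shares were 77%, 49%, 50%, 21% and 81%. Among unchanged genes, 7, 6, 12, 6 and 8 were called. The simulated noise was drawn independently for each gene and library, without classes of library or correlation between genes. In the real data 4952 genes were called between libraries of higher and lower FPKM per fragment, beside set and genotype. The simulation therefore does not measure false calls that come from such structure.

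Other settings that were tried were pseudocounts of 0.1 and 0.5, no filter or a mean FPKM of at least 5, quantile normalization, median-of-ratios scaling, robust variances, library weights, a fold of at least 1.5, each replicate number as a block, fits within 1 set or genotype and leaving out each library in turn. Settings chosen after seeing the data were leaving out the 2 libraries with the lowest correlation to the others, keeping the 18 libraries of lower FPKM per fragment, a term for these 2 classes of library, a clock score as a covariate and the sum of Loxl2 and Gm21451. Values within the libraries of lower FPKM per fragment come from the fit on these 18 libraries in every contrast.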

Results

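Liver RNA was sequenced from C57BL/6 mice that overexpressed L2d13 and from wild-type (WT) mice, with 12 libraries per genotype. L2d13 stands for the form that the labels call L2 delta13. That name is in use for a splice form of lysyl oxidase like 2 (Loxl2) without exon 13, although the labels do not spell L2 out. Loxl2 is a secreted copper enzyme that oxidises lysines of collagen and elastin and so starts their crosslinking. The sample names of both genotypes carry the digit 2 or 4, whose meaning the labels do not give. The 24 libraries therefore form 4 groups of 6, called here set 2 and set 4 of each genotype. The sample names also carry running numbers, and those of each group form a block that does not overlap the others. Their meaning is not given either. Genotype within a set was thus not separated from whatever these numbers follow. Nothing in the labels says that the libraries came from separate animals, so p-values measure the spread between these samples, which may be partly technical.

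The deposited table held FPKM for 18171 genes, and 10532 of them passed the filter on low values and were tested. The FPKM of a library summed to between 550260 and 722980, and between 9463 and 11371 genes reached an FPKM of 1. FPKM carries no read total, so the number of fragments of each library is unknown. The value of 1 fragment could still be compared between libraries from the steps between low FPKM values. By the definition of FPKM, that value is higher where fewer fragments were counted or where the effective gene length is shorter. It lay between 0.981 and 1.018 of the common value in 18 libraries and between 1.025 and 1.243 in the other 6. The cut between them is not sharp, as the nearest libraries on its sides were set 2 WT replicate 1 (1.018 ± 0.0105, SE) and set 4 WT replicate 11 (1.025 ± 0.0104). These 6 were set 2 L2d13 replicate 3, set 2 WT replicate 6 and set 4 WT replicates 9 to 12. As 1 of them was L2d13 and 5 were WT, the values within the other 18 libraries are given beside the pooled ones. The major urinary protein (Mup) genes took 12.7% ± 6.06 (SD, n = 12) of the FPKM sum in L2d13 and 19.6% ± 6.85 (SD, n = 12) in WT.

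The targeted gene was examined first, to check the labels. Loxl2 (gene 94352) had an FPKM of 1.501 ± 0.384 (SD, n = 12) in L2d13 livers and 0.680 ± 0.254 (SD, n = 12) in WT livers, a log2 difference of 0.57. The difference was 0.57 in set 2 and 0.58 in set 4, with all 12 L2d13 libraries above the WT mean of their set. The two-sided permutation test within sets gave p = 2e-05 over the 24 libraries. The exact permutation test gave p = 0.00433 in set 2 and p = 0.00216 in set 4, the latter being the smallest that 924 arrangements of 6 against 6 can give. Within the 18 libraries the log2 difference was 0.54.

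A much larger difference was found in Gm21451 (gene 100862072), an annotated copy of Loxl2 that is classed as an unprocessed pseudogene and was singled out after its values were seen. Its FPKM was 172 ± 69.3 (SD, n = 12) in L2d13 livers, with single libraries between 40.63 and 266.18, and 0.240 ± 0.339 (SD, n = 12) in WT livers, with single libraries between 0.03 and 1.27. The log2 difference was 7.01 ± 0.23 (SE), or 129-fold on the log2(FPKM + 1) scale, with an adjusted p of 1.54e-17. It was 6.68 in set 2 and 7.33 in set 4. With the FPKM of Loxl2 and Gm21451 summed, the log2 difference was 6.38 by the permutation test (p = 2e-05).

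**Figure D1:**
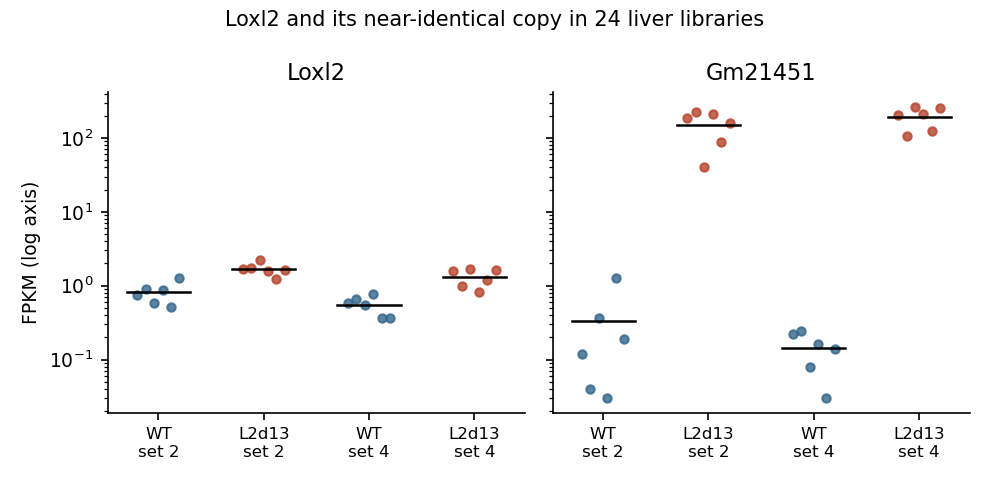
FPKM of Loxl2 and of its annotated copy Gm21451 in each of the 24 libraries by group, on a log axis, where points stand for libraries and bars for group means. Gm21451 lies between 40.63 and 266.18 in the 12 L2d13 libraries and between 0.03 and 1.27 in the 12 WT libraries.

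On GRCm38, Loxl2 lies on chromosome 14 from 69609068 to 69695834 on the plus strand and Gm21451 lies upstream of it on the same strand, from 69390854 to 69480287. The annotated Gm21451 transcript of 2775 bases was identical to the Loxl2-201 transcript over its first 2348 bases, with 0 mismatches. This stretch covered bases 62 to 2409 of Loxl2-201 and stopped at the last base of its exon 12 of 14. Exon 13 of Loxl2 (69692314 to 69692425) and exon 14 with the 3' untranslated region lay outside it. Reads from exons 1 to 12 could thus be counted for either gene, and the FPKM of both is uncertain for that reason.

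**Figure D2:**
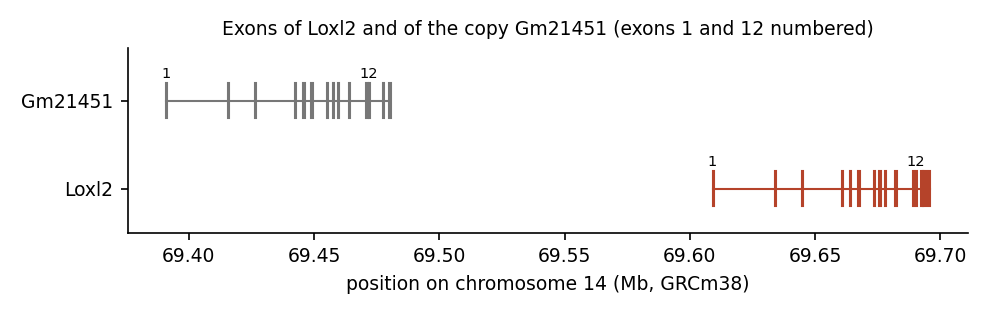
Exons of the Gm21451 and Loxl2 transcripts on chromosome 14, drawn to scale on GRCm38 in megabases, where boxes are exons and lines are introns. The identical stretch of 2348 bases ends with exon 12 in both genes, so Loxl2 exons 13 and 14 have no counterpart in that stretch.

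The neighbourhood of these genes differed far less. Of 17 neighbouring genes that were measured, 10 were tested, with a median log2 difference of 0.21 and a highest of 0.49 for R3hcc1; 4 were called higher and none lower. The other lysyl oxidases fell below the filter and were not tested. Lox had an FPKM of 0.125 ± 0.0989 (SD, n = 12) in L2d13 and 0.0942 ± 0.0514 in WT, and Loxl1 0.439 ± 0.333 and 0.409 ± 0.1598. Loxl3 had 0.518 ± 0.517 and 0.359 ± 0.163, and Loxl4 0.975 ± 0.750 and 0.615 ± 0.313. Loxl4 lay between 0.78 and 2.69 in L2d13 and between 0.37 and 0.63 in WT of set 2, but between 0.22 and 0.70 in L2d13 and between 0.38 and 1.49 in WT of set 4. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were present in all 24 libraries, for example Eif2s3y at 31.0 ± 4.05 (SD, n = 12) in L2d13 and 27.4 ± 7.15 (SD, n = 12) in WT. Their log2 differences were 0.10, 0.20, 0.03 and -0.00 (adjusted p = 0.481, 0.14, 0.732 and 0.979), and the sign of Ddx3y, Kdm5d and Uty changed with the scaling or the libraries used.

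Large differences between L2d13 and WT livers were seen in single genes. Apoa4 (gene 11808), an apolipoprotein of triglyceride-rich particles, was 6.90-fold higher, with an FPKM of 1822 ± 1660 (SD, n = 12) in L2d13 and 186 ± 53.2 in WT. Cidec (gene 14311), which enlarges lipid droplets, was 5.03-fold higher, with 41.3 ± 21.5 against 6.89 ± 3.04. Both changes were seen in all 12 L2d13 libraries against the WT mean of their set.

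Of the 10 genes with the largest rise under the naming rule, which passes over predicted genes such as Gm21451, Apoa4 had a log2 difference of 2.79 ± 0.31 (SE). It was followed by Cgref1, a cell growth regulator with EF-hand domains (2.56 ± 0.17), Derl3, which takes part in the degradation of misfolded proteins of the endoplasmic reticulum (2.52 ± 0.40), Cidec (2.33 ± 0.26) and the steroid hydroxylase Cyp17a1 (2.07 ± 0.25). Next came the contactin-associated protein Cntnap1 (1.86 ± 0.21), the leptin receptor Lepr (1.66 ± 0.40), the hydrolase Abhd2 (1.55 ± 0.45), the translation repressor Eif4ebp3 (1.51 ± 0.22) and Ehhadh, an enzyme of peroxisomal fatty acid oxidation (1.47 ± 0.32). Their adjusted p ran from 2.13e-10 for Cgref1 to 0.0108 for Abhd2. Abhd2 was higher in 11 of the 12 L2d13 libraries and the other genes in 12 of 12. The leptin receptor rise came with a wide spread, at an FPKM of 14.2 ± 16.4 (SD, n = 12) against 2.75 ± 3.48.

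Of the 10 genes with the largest fall, 9 are given here. They were Bglap3, a relative of osteocalcin (log2 -3.29 ± 0.49, SE), the secreted proteoglycan Tsku (-2.55 ± 0.23), the rhythmic phosphatase Noct (-2.31 ± 0.27), Mup17 (-2.22 ± 0.54), and the carbonic anhydrase Car3 (-2.06 ± 0.27). The others were the regulator Tcim (-1.93 ± 0.26), the lipid droplet coat protein Plin4 (-1.73 ± 0.34), Mup15 (-1.73 ± 0.47) and Cyp2c70, which makes the muricholic acids of mouse bile (-1.70 ± 0.29). Their adjusted p ran from 5.66e-08 for Tsku to 0.007 for Mup15. Plin4 and Mup15 were lower in 11 of 12 L2d13 libraries and the others in 12 of 12. Tsku, for example, had an FPKM of 10.5 ± 4.47 (SD, n = 12) in L2d13 and 73.9 ± 49.2 in WT, and Car3 had 324 ± 195 and 1180 ± 435. The Mup genes are near-identical copies between which reads can be split in error, so the values of single Mup genes are uncertain.

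**Figure D3:**
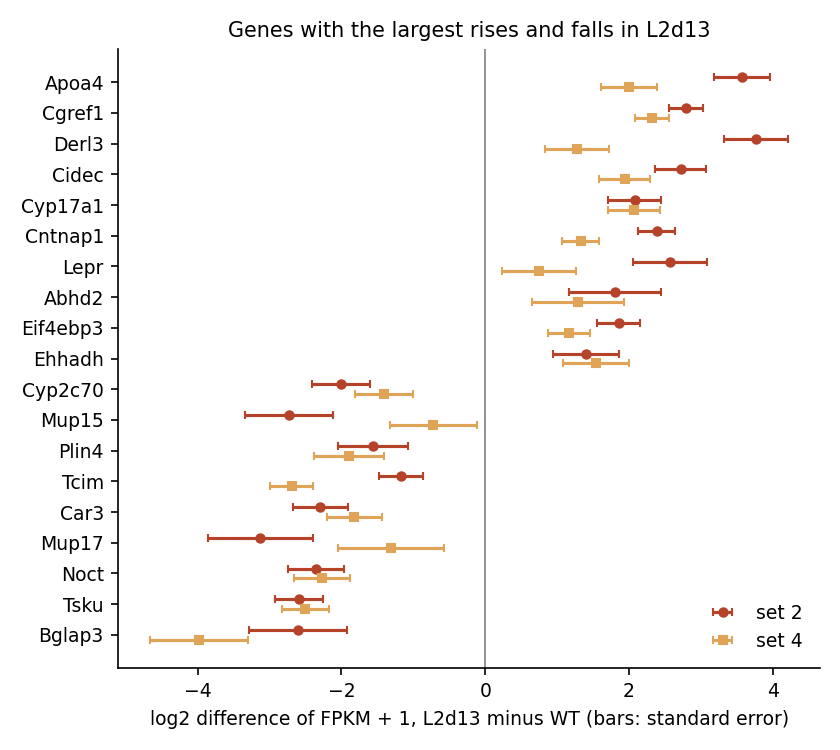
Log2 difference between L2d13 and WT (log2 of FPKM + 1) of 19 of the 20 genes with the largest rise or fall, shown for set 2 (circles) and set 4 (squares), where bars are standard errors. All 19 genes lie on the same side of 0 in both sets, which the rule for naming them requires. Derl3 is farther from 0 in set 2 (3.76) than any other gene that rose.

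In all, limma called 3242 of the 10532 genes different between the genotypes, 2730 higher and 512 lower in L2d13. Of these calls 567 had a fold of at least 1.5. The numbers of list members that rose or fell over both sets, given below, are to be read against these numbers of all genes. The median log2 difference of all tested genes was 0.12, and scaling each library by a median-of-ratios factor moved that median by -0.11. The split moved to 1128 higher and 1162 lower, while quantile normalization gave 1310 and 1079, and all 20 genes of the largest rises and falls remained called with either. Within the 18 libraries 1554 genes were higher and 503 lower, 1649 of the 3242 calls were shared, and 16 of the 20 genes remained called. Abhd2 (log2 0.90 ± 0.47, SE, adjusted p = 0.19), Ehhadh (0.87 ± 0.34, 0.0768), Mup15 (-1.53 ± 0.62, 0.0879) and Mup17 (-1.80 ± 0.71, 0.0835) did not.

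Fatty acid handling moved in more than 1 direction. Of 28 tested genes of fatty acid oxidation and ketone synthesis, 17 rose and 2 fell (19 and 2 when adjusted over the list alone; 10 and 2 with median-of-ratios scaling). The 4 members with the smallest p rose: the microsomal hydroxylase Cyp4a10 (log2 1.07 ± 0.14, SE), the mitochondrial importer of fatty acids Cpt1a (0.94 ± 0.13, from an FPKM of 109 in WT to 203 in L2d13), the peroxisomal thiolase Acaa1a (0.54 ± 0.10) and Ehhadh. The list was called upwards by camera (adjusted p = 0.00521; adjusted p = 0.701 with an estimated correlation), but not with the class of library as a term (adjusted p = 0.081). Of 16 genes of fatty acid synthesis 3 rose and 4 fell, the same numbers as when adjusted over the list alone (2 and 6 with median-of-ratios scaling). The elongase Elovl5 (0.84 ± 0.15) and the mitochondrial carboxylase Acacb (0.60 ± 0.13) rose, while the lipogenic regulator Thrsp (-1.58 ± 0.36) and the desaturase Scd1 (-1.17 ± 0.27) fell. This list was called downwards (adjusted p = 0.0222; adjusted p = 0.51 with an estimated correlation) in 29 of 36 alternative settings as well.

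The list of cholesterol synthesis was called downwards. Of 24 tested members 11 fell and none rose, also when adjusted over the list alone, with a median log2 difference of -0.38. Nsdhl (-1.03 ± 0.16, SE), Fdps (-0.95 ± 0.17) and Hmgcs1 (-1.08 ± 0.20), enzymes of the pathway, were among the 4 with the smallest p. Hmgcs1 for instance stood at an FPKM of 24.6 in L2d13 and 59.8 in WT. Camera called the list downwards (adjusted p = 5.77e-11; adjusted p = 0.237 with an estimated correlation). Lipid droplet and lipid uptake genes were not called as a list (adjusted p = 0.315), with 5 of 16 risen and 1 fallen; the triglyceride lipase Pnpla2 (0.82 ± 0.09) and Cidec had the smallest p.

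Of the lists, that of xenobiotic enzymes had the smallest p. Of 23 tested xenobiotic cytochromes and conjugating enzymes 12 fell and none rose (13 and none when adjusted over the list alone; 13 fell and 1 rose with quantile normalization), and the median log2 difference was -0.52. The glutathione transferases Gstm3 (-1.66 ± 0.19, SE), Gsta2 (-0.87 ± 0.13) and Gstm1 (-0.98 ± 0.15, from an FPKM of 1580 in WT to 761 in L2d13) and the cytochrome Cyp1a2 (-1.08 ± 0.13) had the smallest p. The call held with the preset correlation (adjusted p = 6.93e-12) and with an estimated correlation (adjusted p = 0.00755). Of 17 antioxidant response genes 6 fell and 1 rose, also when adjusted over the list alone (adjusted p = 0.000636; adjusted p = 0.237 with an estimated correlation). Gclc (-1.11 ± 0.15) and Gclm (-0.36 ± 0.08), the subunits of the enzyme that limits glutathione synthesis, and the transketolase Tkt (-0.45 ± 0.09) fell, and the sulfiredoxin Srxn1 (0.61 ± 0.12) rose.

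The lists of lobule position and of sex bias gave mixed results. Of 16 genes of the pericentral zone 6 fell and 4 rose, also when adjusted over the list alone, among them Cyp1a2, the calcium regulator Rgn (-0.82 ± 0.11, SE) and Lect2 (-0.69 ± 0.15), which fell, and the ornithine aminotransferase Oat (0.91 ± 0.16), which rose. The list was called downwards (adjusted p = 0.00883; adjusted p = 0.51 with an estimated correlation). Of 23 male-biased genes 11 fell and none rose (12 and none when adjusted over the list alone), with Mup21 (-1.24 ± 0.20), Mup3 (-0.52 ± 0.11), the elongase Elovl3 (-1.12 ± 0.27) and the steroid dehydrogenase Hsd3b5 (-1.68 ± 0.41) leading (adjusted p = 9.35e-09; adjusted p = 0.237 with an estimated correlation). The call on Mup3 was lost with quantile normalization, and this list shares its Mup genes with the share of urinary protein transcripts given above. Female-biased genes were not called as a list (adjusted p = 0.999), with 3 of 11 risen (1 with either scaling), among them Cyp17a1 and Rtn4 (0.49 ± 0.16).

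In the lists of sugar and of bile acid genes some members rose and others fell. Of 18 genes of glycolysis and glycogen 6 rose and 5 fell, also when adjusted over the list alone, but 2 rose and 6 fell with median-of-ratios scaling and 3 and 5 with quantile normalization. The glycogen targeting subunit Ppp1r3b (-1.61 ± 0.15, SE) and the ketohexokinase Khk (-0.55 ± 0.10) fell, and the liver glycogen synthase Gys2 rose (0.88 ± 0.15). The list was called downwards (adjusted p = 0.025; adjusted p = 0.51 with an estimated correlation; adjusted p = 0.211 within the 18 libraries), although its median was 0.03 and its mean -0.17. Of 19 genes of bile acid synthesis and transport 5 fell and 3 rose, also when adjusted over the list alone (7 and 2 with median-of-ratios scaling). Cyp2c70 and the bile salt export pump Abcb11 (-0.39 ± 0.11) fell, and the sterol hydroxylase Cyp8b1 (0.80 ± 0.10) and the phospholipid flippase Abcb4 (0.43 ± 0.11) rose (adjusted p = 0.0293; adjusted p = 0.479 with an estimated correlation). Of 17 genes of gluconeogenesis and fasting 5 rose and 2 fell (5 and 4 when adjusted over the list alone; 3 and 4 with median-of-ratios scaling and 3 and 3 with quantile normalization), and the list was not called (adjusted p = 0.445). The pseudokinase Trib3 (1.06 ± 0.15) and the transaminase Got1 (0.92 ± 0.15) had the smallest p.

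The lists of clock and of immediate early genes were called downwards, with members of the former moving both ways. Of 19 clock genes 5 fell and 3 rose (5 and 4 when adjusted over the list alone; 8 and 2 with median-of-ratios scaling and 7 and 2 with quantile normalization), and the list was called downwards with the preset correlation (adjusted p = 0.00152) and with an estimated correlation (adjusted p = 0.0341). Noct, Per1 (-1.15 ± 0.23, SE) and the deubiquitinase Usp2 (-0.82 ± 0.18) fell and the repressor Cry2 rose (0.59 ± 0.10). Of 13 immediate early genes 5 fell and none rose, also when adjusted over the list alone (adjusted p = 5.6e-05; adjusted p = 0.353 with an estimated correlation). The mRNA decay factor Zfp36 (-1.09 ± 0.21), the phosphatase Dusp1 (-1.19 ± 0.25), Ier2 (-0.58 ± 0.16) and Jun (-0.75 ± 0.23) had the smallest p.

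The lists of endoplasmic reticulum stress and of the interferon response were called upwards. Of 22 genes of endoplasmic reticulum stress and chaperones 14 rose and 2 fell, also when adjusted over the list alone, with a median log2 difference of 0.63. The lectin chaperone Calr rose from an FPKM of 309 to 545 (0.81 ± 0.09, SE) and Hsp90b1 from 251 to 556 (1.11 ± 0.13); Trib3 and the disulfide isomerase Pdia4 (0.95 ± 0.16) rose too. The list was called upwards (adjusted p = 0.0366, and adjusted p = 0.701 with an estimated correlation) and was called in 25 of 36 alternative settings. It was not called within the 18 libraries (adjusted p = 0.0695) or with a class term (adjusted p = 0.103). Nor was it called without set 2 L2d13 replicate 3 and set 2 WT replicate 6 (adjusted p = 0.0946). Of 25 interferon response genes 12 rose and none fell (14 and none when adjusted over the list alone; 9 and 1 with median-of-ratios scaling), with Oasl1 (1.37 ± 0.18), Ifit3 (0.84 ± 0.15), Ifit2 (0.36 ± 0.06) and Ifit1 (0.83 ± 0.17) leading. That list was called upwards (adjusted p = 0.0381; adjusted p = 0.701 with an estimated correlation) and in 24 of 36 alternative settings.

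Markers of liver cell types depended on the scaling. Of 15 genes of liver endothelium 7 rose and none fell (8 and none when adjusted over the list alone), and 3 rose with median-of-ratios scaling as with quantile normalization. Among those that rose were the hyaluronan receptor Lyve1 (0.99 ± 0.18, SE), Gpr182 (0.77 ± 0.18), Oit3 (0.88 ± 0.22) and Pecam1 (0.48 ± 0.16, not called with either scaling). The list was called upwards (adjusted p = 0.0442; adjusted p = 0.701 with an estimated correlation) and in 20 of 36 alternative settings, but not within the 18 libraries (adjusted p = 0.548), with a class term (adjusted p = 0.0834) or without set 2 L2d13 replicate 3 and set 2 WT replicate 6 (adjusted p = 0.102). The former library stood far above its group in the mean of this list. Neither Kupffer cell and macrophage genes (adjusted p = 0.126, 4 of 15 risen, 1 with either scaling) nor stellate cell and fibroblast genes (adjusted p = 0.524, 3 of 16 risen) were called. The scavenger receptor Cd163 (0.67 ± 0.19) and Clec4f (0.61 ± 0.20) of the former and Lrat (0.49 ± 0.10) and Pdgfra (0.41 ± 0.10) of the latter had the smallest p. Of 13 hepatocyte markers 1 fell, Ttr (-0.69 ± 0.12), also when adjusted over the list alone; 3 fell with median-of-ratios scaling, and 4 rose and 1 fell with quantile normalization. Hnf4a (-0.28 ± 0.11, adjusted p = 0.0559), Alb (-0.30 ± 0.14, adjusted p = 0.112) and Apoa2 (-0.38 ± 0.18, adjusted p = 0.12) did not pass. Alb and Apoa2 changed sign with quantile normalization, and the difference of Alb was -0.185 without set 2 L2d13 replicate 3. The hepatocyte list was called downwards (adjusted p = 0.0293, and adjusted p = 0.51 with an estimated correlation), also with a class term (adjusted p = 0.000252). It was not called within the 18 libraries (adjusted p = 0.126) or without set 2 L2d13 replicate 3 and set 2 WT replicate 6 (adjusted p = 0.0946). The hepatocyte list pointed the other way in 1 of 36 alternative settings. Of 4 adipocyte markers Car3 and the adrenergic receptor Adrb3 (-1.19 ± 0.30) fell and the fatty acid binding protein Fabp4 (0.57 ± 0.20) rose. Cfd (-1.16 ± 0.47, adjusted p = 0.0613) did not pass over all genes but did when adjusted over the list alone. The adipocyte list was called downwards (adjusted p = 0.00883; adjusted p = 0.237 with an estimated correlation; adjusted p = 0.132 within the 18 libraries) and was called in 31 of 35 alternative settings.

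Fibrillar collagens, the usual substrate context of lysyl oxidases, were not called over both sets. Of 12 genes of fibrillar collagen and matrix none passed (adjusted p = 0.792 for the list), and the lowest p belonged to the proteoglycan Dcn, at an FPKM of 75.5 ± 32.7 (SD, n = 12) in L2d13 and 56.5 ± 15.1 in WT (adjusted p = 0.0528), and to Postn (0.25 ± 0.10, adjusted p = 0.0588). In set 2, 4 of the 12 rose (1 with either scaling and 5 within the libraries of lower FPKM per fragment), with the list not called (adjusted p = 0.231). Of 9 basement membrane genes 3 rose, also when adjusted over the list alone, including Col4a1 (0.55 ± 0.13, SE) and Col4a2 (0.46 ± 0.11), with the list not called (adjusted p = 0.612). Of 9 matrix remodelling enzymes 1 rose and 1 fell (adjusted p = 0.693), the lysyl hydroxylase Plod1 (0.23 ± 0.07) and the prolyl hydroxylase subunit P4ha1 (-0.63 ± 0.18). Over both sets camera called 16 of 42 lists, 4 upwards and 12 downwards, and 2 of them, xenobiotic metabolism and the clock, also with an estimated correlation.

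Within set 2, Derl3 rose from an FPKM of 3.54 ± 2.65 (SD, n = 6) in WT to 63.7 ± 51.4 in L2d13, Apoa4 from 210 ± 33.6 to 2962 ± 1681 and Lepr from 3.05 ± 2.45 to 24.9 ± 17.5. The 5 largest rises were Derl3 (log2 3.76 ± 0.44, SE), Apoa4 (3.57 ± 0.38), Cgref1 (2.79 ± 0.24), Cidec (2.72 ± 0.35) and Lepr (2.58 ± 0.51). The 5 largest falls were Mup17 (-3.13 ± 0.74), Mup15 (-2.73 ± 0.61), Bglap3 (-2.60 ± 0.68), Tsku (-2.59 ± 0.33) and Mup18 (-2.39 ± 0.48). All 10 were seen in 6 of 6 L2d13 libraries, and their adjusted p ran from 1.06e-07 for Cgref1 to 0.0126 for Bglap3.

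Of the lists, xenobiotic enzymes had the smallest p in set 2, with 13 of 23 members fallen and none risen (14 and none when adjusted over the list alone), among them Cyp1a2, Gstm3, Cyp2c50 and Gsta2 (adjusted p = 8.59e-19; adjusted p = 0.000199 with an estimated correlation). Male-biased genes fell with 8 of 23 members (9 adjusted over the list alone), led by Mup11, Mup17, Elovl3 and Mup21 (adjusted p = 1.92e-13; adjusted p = 0.0569 with an estimated correlation). Cholesterol synthesis fell with 7 of 24 members (9 adjusted over the list alone), among them Nsdhl, Insig1 and Fdps (adjusted p = 5.14e-11; adjusted p = 0.229 with an estimated correlation). Pericentral genes fell with 7 of 16 members and no rise (7 and 1 adjusted over the list alone), led by Cyp1a2, Rgn, the carboxylate carrier Slc13a3 and Cyp2a5 (adjusted p = 8.66e-09; adjusted p = 0.0569 with an estimated correlation). Endoplasmic reticulum chaperones rose with 12 of 22 members and no fall (14 adjusted over the list alone), led by Hsp90b1 (1.42 ± 0.16, SE), Calr (0.97 ± 0.12), Pdia4 (1.454 ± 0.18) and Sdf2l1 (1.83 ± 0.25) (adjusted p = 1.1e-05; adjusted p = 0.3 with an estimated correlation).

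Marker lists of other cells moved in set 2 too. Of these, liver endothelium rose with 4 of 15 members (5 adjusted over the list alone; adjusted p = 0.00655; adjusted p = 0.678 with an estimated correlation), and stellate cells and fibroblasts with 5 of 16 (9 adjusted over the list alone; 2 with either scaling; adjusted p = 0.0332; adjusted p = 0.678 with an estimated correlation; adjusted p = 0.155 within the libraries of lower FPKM per fragment). Of 13 hepatocyte markers 1 fell, also when adjusted over the list alone (adjusted p = 0.00153; adjusted p = 0.27 with an estimated correlation), but 2 rose and none fell with quantile normalization, and none passed within the libraries of lower FPKM per fragment, where the list stayed called downwards (adjusted p = 0.0105). In all, 1364 genes were higher and 224 lower, and camera called 15 lists, of which 1 was also called with an estimated correlation. Median-of-ratios scaling gave 304 higher and 389 lower, with a shift of -0.16 in the median over all genes, and quantile normalization 413 and 414. Within the libraries of lower FPKM per fragment 1869 were higher and 306 lower with 1422 of the 1588 calls shared, and the 10 genes remained called. Without set 2 WT replicate 4 the count was 972.

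Within set 4, Nr1d1, a clock repressor, rose from an FPKM of 2.73 ± 1.34 (SD, n = 6) in WT to 29.0 ± 10.5 in L2d13, and Dbp, a clock-driven activator, from 1.003 ± 0.792 to 14.03 ± 14.1. The 5 largest rises were Nr1d1 (log2 2.999 ± 0.36, SE), Dbp (2.49 ± 0.44), Cgref1 (2.32 ± 0.24), Cyp17a1 (2.07 ± 0.37) and Apoa4 (2.001 ± 0.38). The 5 largest falls included Bglap3 (-3.98 ± 0.68), Tcim (-2.69 ± 0.30), Tsku (-2.50 ± 0.33) and Bcl6 (-2.45 ± 0.39), a repressor that acts in growth hormone signalling. All 10 were seen in 6 of 6 L2d13 libraries, and their adjusted p ran from 2.21e-06 for Cgref1 to 0.0018 for Apoa4.

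Of 19 clock genes in set 4, 8 fell and 5 rose (9 and 5 when adjusted over the list alone; adjusted p = 0.0084; adjusted p = 0.33 with an estimated correlation). Nr1d1 and Nr1d2 (1.31 ± 0.19, SE) rose, and the repressor Cry1 (-0.91 ± 0.14) fell. A clock score differed by 1.76 between L2d13 and WT of set 4 (exact permutation test, p = 0.00216). A different time of day of collection was therefore not separated from genotype in this set. Cholesterol synthesis fell with 9 of 24 members (11 adjusted over the list alone), among them Hmgcs1, Fdps and Nsdhl (adjusted p = 4.24e-07; adjusted p = 0.488 with an estimated correlation). Immediate early genes fell with 5 of 13, also when adjusted over the list alone, namely Zfp36 (-1.44 ± 0.29), Dusp1, Egr1 (-1.62 ± 0.39) and Fos among the first 4 (adjusted p = 1.33e-05; adjusted p = 0.405 with an estimated correlation). Xenobiotic enzymes fell with 6 of 23 and rose with 1, also when adjusted over the list alone, led by the falls of Gstm3, Cyp1a2, Gsta2 and Gstm1 (adjusted p = 4.98e-05; adjusted p = 0.239 with an estimated correlation). Fatty acid oxidation rose with 11 of 28 and fell with 1 (16 and 1 adjusted over the list alone; 7 and 1 with median-of-ratios scaling, and 1 risen within the 18 libraries), led by Cyp4a10, Cpt1a, Cyp4a32 and Cpt2 (adjusted p = 0.000911; adjusted p = 0.654 with an estimated correlation). Amino acid and urea metabolism rose with 8 of 23 (15 and 1 fall adjusted over the list alone; 2 with median-of-ratios scaling, 5 with quantile normalization and 2 within the 18 libraries), led by the methionine adenosyltransferase Mat1a (1.13 ± 0.20), Got1, Asl and Slc25a15 (adjusted p = 0.000911; adjusted p = 0.651 with an estimated correlation). Asl and Slc25a15 were not called with median-of-ratios scaling.

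Kupffer cell and macrophage markers were called upwards in set 4 with 1 of 15 members risen, Cd163, also when adjusted over the list alone (adjusted p = 0.00457; adjusted p = 0.742 with an estimated correlation; adjusted p = 0.78 within the libraries of lower FPKM per fragment). In all, 1090 genes were higher and 313 lower, and of the 12 lists called none was called with an estimated correlation. Median-of-ratios scaling gave 617 higher and 626 lower and quantile normalization 705 and 544. In this set 4 of the 6 WT libraries belong to those with a higher FPKM per fragment, so the comparison within the others sets 6 L2d13 libraries against 2 WT libraries. There 220 genes were higher and 299 lower, 276 of the 1403 calls were shared and the 10 genes of the largest rises and falls remained called. Cholesterol synthesis was no longer called (adjusted p = 0.78), nor were fatty acid oxidation (adjusted p = 0.255) and the clock (adjusted p = 0.238). The clock median did not shrink there, at -0.533 against -0.463 over all libraries of the set. That of cholesterol synthesis moved from -0.533 to -0.0373 and that of fatty acid oxidation from 0.403 to 0.116. Immediate early genes (adjusted p = 0.00177), amino acid metabolism (adjusted p = 3.66e-05) and xenobiotic enzymes (adjusted p = 0.0488) were still called. Single members named above were lost there too: Hmgcs1, Fdps, Nsdhl, Gstm3, Cyp1a2, Gsta2, Gstm1, Cyp4a10, Cpt1a, Cpt2, Mat1a, Got1, Slc25a15, Zfp36 and Egr1 were not called. The count also moved with single libraries, to 2434 without set 4 WT replicate 8, 833 without WT replicate 9, 921 without WT replicate 10, 842 without WT replicate 11 and 910 without L2d13 replicate 9.

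The genotype differences of the sets overlapped, and no libraries are shared between them. The spread was estimated from all 24 libraries in 1 fit, however, so the calls of the sets are not fully independent. Both sets also had a median log2 difference above 0 (0.158 in set 2 and 0.0778 in set 4). The numbers from independent lists are thus not a strict reference. Of the genes called in each, 539 were higher in both, against 141 from independent lists of the same lengths, and 112 were lower in both, against 6.66; 3 genes were called in opposite directions. Across the 10532 genes, which are not independent replicates, the log2 differences of the sets correlated with a Pearson r of 0.638 and a Spearman rho of 0.583.

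The test of the difference between the sets found 16 genes. Nr1d1 rose in L2d13 livers of set 4 and showed a log2 difference of -0.11 in set 2 (interaction 3.11 ± 0.51, SE, adjusted p = 0.00541), and Nr1d2 followed with 1.31 in set 4 and -0.25 in set 2 (1.56 ± 0.27, adjusted p = 0.00982). The clock-related repressor Nfil3 (-1.83 ± 0.34, adjusted p = 0.0212) fell from an FPKM of 38.2 ± 12.6 (SD, n = 6) in WT to 16.6 ± 5.63 in L2d13 of set 4. It stood at 26.1 ± 8.64 and 40.7 ± 10.3 in set 2. The clock score differed between L2d13 and WT by 1.76 in set 4 and by -0.637 in set 2 (exact permutation test, p = 0.00216 and 0.0411). A different time of day of collection was thus not separated from genotype, for these clock genes or for any other gene of this test. Parp16, a transferase of the endoplasmic reticulum membrane, rose in set 2 and fell in set 4 (-2.03 ± 0.24, adjusted p = 0.000142). The chaperone cofactors Manf (-1.66 ± 0.34) and Sdf2l1 (-1.81 ± 0.36) rose in set 2, Manf from 44.2 ± 16.4 to 140 ± 24.9. They had log2 differences of 0.04 and 0.02 in set 4 (both interactions at adjusted p = 0.0368). Slc13a3 fell in set 2 and had 0.19 in set 4 (0.96 ± 0.20, adjusted p = 0.0417).

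**Figure D4:**
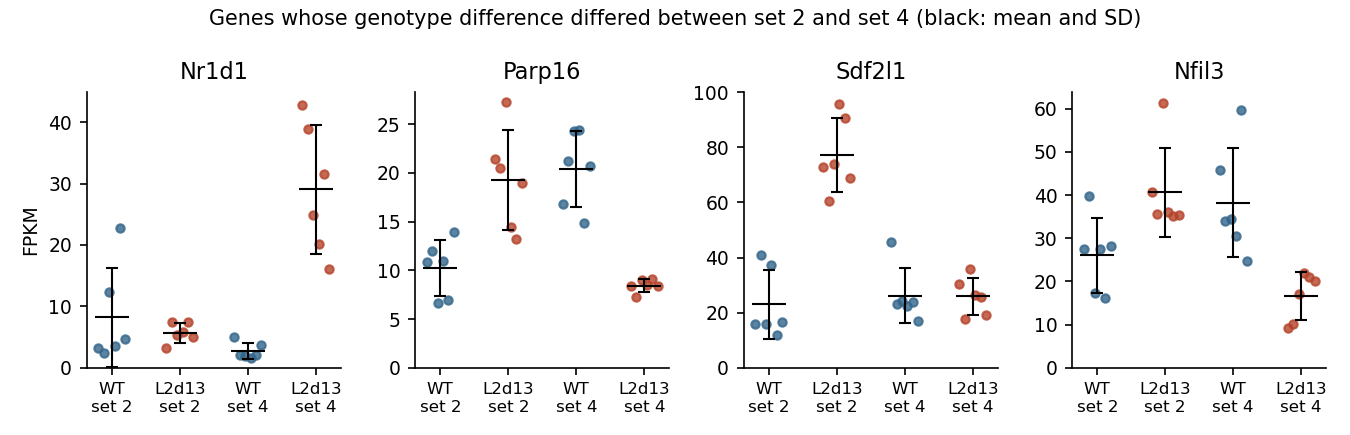
FPKM of 4 genes whose difference between L2d13 and WT differed between the sets, in each of the 24 libraries by group, where points are libraries and black bars give mean and SD (n = 6). Nr1d1 has means of 2.73 in WT and 29.0 in L2d13 in set 4 but 8.20 and 5.71 in set 2, and the mean of Nfil3 is lower in L2d13 than in WT in set 4 and higher in set 2.

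The lists with the smallest p in this test were the pericentral zone, higher in set 4 than in set 2 relative to WT (1 member passed upwards, Slc13a3, and 4 upwards and 1 downwards when adjusted over the list alone; adjusted p = 2.5e-11; adjusted p = 0.0465 with an estimated correlation). Endoplasmic reticulum stress and chaperones came next, lower (2 members, Manf and Sdf2l1, and 10 when adjusted over the list alone; adjusted p = 1.94e-07; adjusted p = 0.429 with an estimated correlation), and then xenobiotic enzymes, higher (no member, and 3 when adjusted over the list alone; adjusted p = 7.37e-06; adjusted p = 0.0667 with an estimated correlation). Camera called 20 lists and fry 0. Within the libraries of lower FPKM per fragment 67 genes were called with 10 of the 16 shared, and Nr1d1 (2.89 ± 0.71, SE, adjusted p = 0.0636), Nr1d2 (1.55 ± 0.36, 0.0541), Slc13a3 (0.96 ± 0.23, 0.0636), Manf (-1.71 ± 0.42, 0.0645), Cry1 (-1.01 ± 0.26, 0.0675) and Ackr2 (-0.85 ± 0.21, 0.0639) were not, with differences near those over all libraries and larger standard errors. Median-of-ratios scaling kept 12 of the 16 and ended the calls on Manf and Sdf2l1 (adjusted p = 0.106 and 0.0688). Single libraries moved the count to 6 without set 4 L2d13 replicate 8 or set 2 WT replicate 5, 7 without set 4 L2d13 replicate 7 or 12, 8 without set 2 L2d13 replicate 1 or 4 or set 4 WT replicate 9, and 9 without set 2 L2d13 replicate 2, set 2 WT replicate 3 or set 4 WT replicate 10.

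The sets themselves differed too. Over both genotypes, set 4 had more Mup12 (log2 2.29 ± 0.34, SE), Selenbp2 (2.67 ± 0.54), Mup9 (4.26 ± 1.21), Mup7 (2.23 ± 0.46) and Mup1 (2.23 ± 0.50). It had less of the female-biased cytochromes Cyp2a4 (-2.83 ± 0.56), Cyp2c40 (-2.12 ± 0.40) and Cyp2b9 (-1.63 ± 0.39), of the hepcidin Hamp2 (-1.83 ± 0.31) and of Lepr (-1.57 ± 0.40), with adjusted p between 0.000517 and 0.0371. Hamp2, for instance, had an FPKM of 77.6 ± 74.6 (SD, n = 12) in set 2 and 20.1 ± 14.2 in set 4. Selenbp2, Mup7, Hamp2 and Cyp2b9 showed this in 12 of 12 set 4 libraries, Mup12, Mup1, Cyp2a4, Cyp2c40 and Lepr in 11 and Mup9 in 9.

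Male-biased genes rose in set 4 with 10 of 23 members (12 and 1 fall adjusted over the list alone), led by Susd4, Mup12, Selenbp2 and Mup7 (adjusted p = 4.85e-27; adjusted p = 0.00802 with an estimated correlation). Cholesterol synthesis rose with 5 of 24 (15 adjusted over the list alone), led by Msmo1, Nsdhl, Insig1 and Cyp51 (adjusted p = 2.56e-28; adjusted p = 0.025 with an estimated correlation). Acute phase genes rose with 3 of 26 (5 adjusted over the list alone), Saa4, Saa1 and Orm3, with Fgb at 0.34 ± 0.11 not past the threshold (adjusted p = 1.25e-12; adjusted p = 0.0819 with an estimated correlation). Several lists of other cells were called downwards, with falls of 12 of 15 Kupffer cell and macrophage genes (15 adjusted over the list alone), led by C1qa, Clec4f, C1qb and Timd4 (adjusted p = 2.63e-10; adjusted p = 0.177 with an estimated correlation) and 10 of 12 genes of fibrillar collagen and matrix (11 adjusted over the list alone), led by Sparc, Col1a2, Postn and Col3a1 (adjusted p = 2.48e-09; adjusted p = 0.109 with an estimated correlation). The fall extended to 7 of 15 genes of liver endothelium (15 adjusted over the list alone; adjusted p = 2.68e-08; adjusted p = 0.194 with an estimated correlation) and 8 of 16 of stellate cells and fibroblasts (14 adjusted over the list alone; adjusted p = 1.68e-07; adjusted p = 0.177 with an estimated correlation). Within the libraries of lower FPKM per fragment none of the Kupffer, endothelium and cholesterol members passed, although these lists stayed called (adjusted p = 0.000124, 0.000321 and 7.02e-06), while 5 genes of fibrillar collagen and matrix and 3 of stellate cells and fibroblasts fell and 3 male-biased genes rose.

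In all, 59 genes were higher and 582 lower in set 4. With median-of-ratios scaling 159 were higher and 175 lower, with a shift of 0.14 in the median over all genes, and with quantile normalization 108 and 164. Within the libraries of lower FPKM per fragment 24 were higher and 89 lower, 91 of the 641 calls were shared, and Mup9, Mup7, Mup1, Selenbp2, Cyp2b9 and Lepr were not called. The call on Mup9 was also lost with quantile normalization and without any of several single libraries. The count moved to 1446 without set 4 WT replicate 8, 977 without set 4 WT replicate 7, and 308 without set 4 WT replicate 11. It was 314, 416, 361, 390 and 412 without set 4 L2d13 replicates 7, 8, 10, 11 and 12, 347 and 403 without set 2 L2d13 replicates 1 and 2, and 376 without set 2 WT replicate 2.

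In WT livers alone the sets differed in 20 genes, 9 higher and 11 lower in set 4. Of 25 interferon response genes 3 fell (18 when adjusted over the list alone; 1 with either scaling), with the list called downwards (adjusted p = 1.32e-12; adjusted p = 0.0806 with an estimated correlation). Of 15 Kupffer cell and macrophage genes none passed over all genes and 15 fell when adjusted over the list alone (adjusted p = 5.5e-18; adjusted p = 0.11 with an estimated correlation). Camera called 21 lists, none with an estimated correlation. Within the libraries of lower FPKM per fragment, 5 WT of set 2 against 2 of set 4, 1 gene was called. Without set 4 WT replicate 8 the count was 82, and it was 11, 11 and 9 without set 4 WT replicates 7, 10 and 11 and 8, 7, 10 and 12 without set 2 WT replicates 2, 3, 5 and 6.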

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

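The splits of the libraries and the tests of neighbouring genes and of Loxl2 against Gm21451 were set before their results were seen. So was that of the 20 named genes within 18 libraries, although this setting was added after the data had been looked at. The tests of the clock score, of shared sequence, of the share of fragments, of the share of higher genes within 18 libraries or with a class term, of other cell types and of fasting were chosen only after the result was seen. Single libraries that stood far from the 5 others of their group were looked for in 260 groups of values. Chance marks about 1 in 20 such groups, or 13, and 27 were found. Set 2 L2d13 replicate 3 accounted for 6 and set 2 WT replicate 6 for 5.

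Both of these libraries had more genes at an FPKM of 1 (11371 and 10713), a lower median correlation with the other libraries (0.934 and 0.925) and a higher FPKM per fragment (1.08 and 1.24) than the rest of their groups. Set 2 L2d13 replicate 3 also had an Alb FPKM of 11018, against at least 23035 in the rest of its group, and the highest Derl3 (167.26 FPKM), Nfil3 (61.29) and mean of the liver endothelium list (log2 4.40), and set 2 WT replicate 6 stood apart in Cntnap1 (1.14) and Cyp2c70 (49.98). In set 2 L2d13 replicate 5, Cgref1 (7.13), Cidec (19.56) and Cntnap1 (1.81) were lowest. In set 2 WT, replicate 5 was highest in Gm21451 (1.27) and Dbp (7.75), and replicate 2 was lowest in Eif4ebp3 (35.54) and highest in the mean of fatty acid oxidation and ketone synthesis (log2 7.40). In set 4 WT, replicate 8 was highest in Lepr (11.67) and Tsku (116.97) and replicate 7 in Slc13a3 (2.36) and Sdf2l1 (45.7). In set 4 L2d13, replicate 11 was lowest in Mup17 (173.91) and Mup15 (1969.65) and highest in Cyp2b9 (0.71), and replicate 8 was lowest in Parp16 (7.21) and highest in the mean of fatty acid synthesis (log2 5.15).

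The genotype difference itself differed between set 4 and set 2 by the interaction test in 16 genes, among them by a log2 value of 3.11 for Nr1d1, 1.56 for Nr1d2, 0.96 for Slc13a3, -2.03 for Parp16, -1.83 for Nfil3, -1.81 for Sdf2l1 and -1.66 for Manf. They also included Wfdc2 (-1.27), Creb3l2 (-1.25), Slc45a3 (-1.10), Septin11 (-0.995), Cry1 (-0.99), Piga (-0.96), Ackr2 (-0.96) and Lonrf3 (-0.61). Lists that differed were pericentral zonation (camera adjusted p = 2.5e-11; adjusted p = 0.0465 with an estimated correlation), endoplasmic reticulum stress and chaperones (camera adjusted p = 1.94e-07; adjusted p = 0.429 with an estimated correlation) and xenobiotic enzymes (camera adjusted p = 7.37e-06; adjusted p = 0.0667 with an estimated correlation).

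Chance assignment of libraries was tested for each of the 6 comparisons by 100 splits, the real one included, that were counted for as many genes called. Each count lay under the bound set before, so few random splits reached the real number. The splits cannot part genotype or set from the class of library or from the blocks of running numbers in the sample names. Chance is not called excluded where another split called more genes. Over both sets 1 of 100 splits gave as many (real 3242, highest other 2813), within set 2 it was 1 (1588 and 927), within set 4 it was 2 (1403 and 1989), for the difference between sets 1 (16 and 1), between the sets 3 (641 and 1261) and between the sets in WT 3 (20 and 1713). No gene was called in 96, 90, 90, 98, 94 and 94 of the other splits. The highest other splits placed 6, 2, 4, 4, 5 and 4 of the libraries of higher FPKM per fragment on 1 side, and those within set 4, between the sets and between the sets in WT called more genes than the real groups did. These libraries thus form a class that goes with many called genes. Most of them are set 4 WT, and their FPKM sum and mean Mup share were higher too. A higher FPKM per fragment can also come from fewer counted fragments. What sets the class apart was thus not separated. Values within the other 18 libraries are given beside the pooled ones for that reason.

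Gm21451 was high in every L2d13 library and near 0 in every WT library. Transcription of the whole neighbourhood was excluded, as the median log2 difference of the tested neighbours was 0.21 against 7.01 for Gm21451. The test of shared sequence found 2348 identical bases that end where exon 13 of Loxl2 would follow, so transcripts of an L2d13 construct may have been counted for Gm21451, a hypothesis that these values cannot separate from transcription of the copy itself. Whether Loxl2 values follow Gm21451 within the 12 L2d13 libraries was left open by a Spearman rho of 0.161 (permutation p = 0.62). The Pearson r was -0.15, and 0.52 without set 2 L2d13 replicates 3 and 5, which lay farthest out.

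More genes were called higher than lower in L2d13, 84.2% of 3242. Without the 6 libraries of higher FPKM per fragment, 75.5% were higher over both sets and 85.9% in set 2. With a class term these shares were 85.9% and 87.5%. These libraries were thus not needed for the excess in set 2. Both genotypes of set 2 held equally many of them, so a class term could not move the differences there and decided nothing. The shares over both sets cannot exclude these libraries as a cause in set 4. In set 4 they were left open as the whole cause. The share there was 42.4% within the other libraries, 6 L2d13 against 2 WT, but 73.3% with a class term. Within the 18 libraries the median log2 difference of all tested genes was 0.0623 over both sets, 0.131 in set 2 and -0.0547 in set 4. The result over both sets there thus rested on set 2. A few abundant genes that take a different share of the fragments were left open as the whole cause. The 20 genes with most fragments would raise all other genes by a log2 value of 0.0878 ± 0.0235 (SE) and the first 10 by 0.0493 ± 0.0128, against a median of 0.116 over all tested genes, so the answer depends on how many genes and which transcript length are taken. Median-of-ratios scaling centres the differences and decides nothing here. More RNA of other liver cell types in L2d13 was left open, since the smallest median of the 3 marker lists lay 0.0854 above that of all tested genes, which is between the bounds set for the test. An effect of L2d13 on the amount of RNA was not tested.

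The 20 genes with the largest differences over both sets were examined for technical causes as a set. A different time of day was left open in part. A clock score differed by -0.637 in set 2 (exact p = 0.0411) and by 1.76 in set 4 (exact p = 0.00216), in opposite directions. With the score as a covariate the 20 genes remained called, for example Apoa4 (log2 2.97 ± 0.32, SE) and Tsku (-2.46 ± 0.24). A change in proportion to the score would turn in sign between the sets, which argues against it as the whole cause for these 20 genes. They were chosen for the same sign in both sets, however, and the clock list was called over both sets. Effects of time of day that the score does not follow therefore stay open. Without the 6 libraries of higher FPKM per fragment 16 of the 20 genes remained called, so the differences of those 16 did not rest on these libraries alone. The 20 genes were chosen over all libraries, those kept here included, so this check is not independent of the choice. It cannot exclude that the 6 libraries added to the differences. Abhd2 (log2 0.90), Ehhadh (0.87), Mup17 (-1.80) and Mup15 (-1.53) were not called without them, and for these genes this cause was left open. A longer fast of 1 genotype was left open by a median of the gluconeogenesis and fasting list of 0.107 above that of all genes, whose members went both ways. L2d13 itself stays among the open explanations.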

How the results depend on the processing

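Values within the 18 libraries of lower FPKM per fragment, without the 2 libraries farthest from the others, with a class term, with the clock score and of Loxl2 plus Gm21451 come from settings added only after the data were seen; the other alternatives were planned. Of 10965 values of named genes under alternatives, 10387 kept direction and side of the threshold, 419 were no longer past it, 140 came to pass it and 19 turned in sign. The count of genes over both sets stayed within 1.5 times of 3242 except with library weights (5508), a fold of at least 1.5 (567) and the 18 libraries (2057). For set 2 it was 827 with quantile normalization, 693 with median-of-ratios scaling, 3775 with library weights, 545 with a fold of at least 1.5, 2568 with a class term and 913 in a fit on its 12 libraries only. For set 4 it was 5289 with library weights, 571 with a fold of at least 1.5, 2624 without the 2 libraries, 5.2e2 within the 18 (220 higher and 299 lower) and 915 with a class term. The difference between sets had 6 genes with no filter, 9 with a mean FPKM of at least 5, 341 with library weights and 67 within the 18 libraries. The sets differed in 263 genes at a mean FPKM of at least 5, 272 with quantile normalization, 334 with median-of-ratios scaling, 2697 with library weights, 167 with a fold of at least 1.5 and 113 within the 18 libraries, and in WT in 9, 1468 with library weights, 1 within the 18 libraries and 7 in a fit on the WT libraries only. Lists called fell from 16 to 2 with an estimated correlation. Fewer libraries or genes enter some of these settings; otherwise the cause was not tested.

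Leaving out single libraries gave 2733 (set 4 WT replicate 11) to 3846 (set 4 WT replicate 8) genes over both sets, 972 (set 2 WT replicate 4) to 1824 (set 4 WT replicate 8) in set 2 and 833 (set 4 WT replicate 9) to 2434 (set 4 WT replicate 8) in set 4. It gave 6 (set 4 L2d13 replicate 8) to 19 (set 4 L2d13 replicate 10) for the difference between sets, 308 to 1446 between the sets (set 4 WT replicates 11 and 8) and 7 to 82 in WT (set 2 WT replicate 3 and set 4 WT replicate 8). Lists called ranged from 11 (set 2 WT replicate 5) to 18 (set 4 L2d13 replicate 8), and the log2 difference of Loxl2 from 0.54 (set 2 L2d13 replicate 3) to 0.60 (set 2 WT replicate 6).

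Signs turned mostly in genes near 0. Uty became positive with a pseudocount of 0.1 (0.00120), library weights (0.0239), a class term (0.0458) and the clock score (0.0108), within the 18 libraries (0.0367), without the 2 libraries (0.0476) and without set 2 L2d13 replicate 6 (0.00306), set 4 L2d13 replicate 10 (0.00752), set 2 WT replicate 6 (0.0567, the highest over left-out libraries; the lowest was -0.0385 without set 2 WT replicate 5) and set 4 WT replicates 8 (0.0130) and 10 (0.00203). Ddx3y became negative with quantile normalization (-0.00675), median-of-ratios scaling (-0.0276) and within the 18 libraries (-0.0304), and Kdm5d with quantile normalization (-0.0888) and median-of-ratios scaling (-0.0635). With quantile normalization Alb (0.176) and Apoa2 (0.00208) turned positive over both sets, and with median-of-ratios scaling Plod1 turned positive between the sets (0.0200). The cause was not tested.

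L2d13 and WT share replicate numbers within each set, but the numbers do not pair the libraries: of 12 same-numbered pairs 4 correlated above 0.1 (range -0.604 to 0.26) and 1 correlated best with its own number. With the number as a replicate block 2526 genes were called over both sets, 807 in set 2 and 679 in set 4. Read totals are unknown, so what depth limits was not measured; low genes move in steps of single fragments.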

Other observations

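No test in this part was chosen only after the result was seen except where 18 libraries or a class of library are named. Amino acid and urea genes leaned upwards without a call as a list (adjusted p = 0.0741 over both sets): of 23 genes 9 rose and 1 fell (14 and 2 when adjusted over the list alone). The methionine adenosyltransferase Mat1a (log2 1.05 ± 0.14, SE) went from an FPKM of 1144 in WT to 2337 in L2d13, and the urea cycle enzyme Asl (0.79 ± 0.13) from 582 to 991; the list was called within the 18 libraries (adjusted p = 0.0372) and in 9 of 36 alternative settings, but not with the class of library as a term (adjusted p = 0.574). With median-of-ratios scaling 6 of the 23 rose and 2 fell. Of 17 periportal genes 4 rose (3 when adjusted over the list alone; 2 with median-of-ratios scaling; adjusted p = 0.637), among them Cps1 (1.01 ± 0.27), which starts the urea cycle, and Igfbp2 (0.56 ± 0.15). Of 14 genes of the growth hormone and IGF axis 2 rose and 2 fell, also when adjusted over the list alone (adjusted p = 0.117), with a fall of Bcl6 (-1.59 ± 0.32) and a rise of Igfbp2. Of 22 apolipoprotein genes 5 rose and 2 fell, also when adjusted over the list alone (adjusted p = 0.32): Apoa4 was among those that rose. With median-of-ratios scaling 1 of the 22 rose and 6 fell.

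Some genes of epithelial junctions and some TGF-beta targets were called higher, without a call as a list. Of all 10532 tested genes 2730 were called higher over both sets. Rises of some members of a list therefore say little about that list, here and in the paragraphs beside this one. Of 13 junction genes 6 rose and none fell, also when adjusted over the list alone (2 with median-of-ratios scaling and 3 with quantile normalization; adjusted p = 0.315), led by the tight junction proteins Ocln (0.54 ± 0.11, SE) and Tjp1 (0.47 ± 0.10), and of 13 TGF-beta targets 4 rose (7 when adjusted over the list alone; adjusted p = 0.445), led by Id2 (0.75 ± 0.15) and Smad6 (0.61 ± 0.15). Of 26 acute phase genes 2 rose and 2 fell, also when adjusted over the list alone (adjusted p = 0.132), with Il1rn (0.80 ± 0.13) up and Saa4 (-0.84 ± 0.17) down. Of 28 complement and coagulation genes 2 fell, also when adjusted over the list alone (6 with median-of-ratios scaling; adjusted p = 0.1), Mbl2 (-0.46 ± 0.12) and C1s1 (-0.20 ± 0.06). Of 13 heat shock genes 3 rose and 2 fell, also when adjusted over the list alone (1 and 2 with median-of-ratios scaling; adjusted p = 0.563), with Hspe1 (0.51 ± 0.11) up and Hspa1a (-0.97 ± 0.23) down. Of 8 p53 targets 3 rose and 2 fell, also when adjusted over the list alone (2 and 3 with median-of-ratios scaling; adjusted p = 0.445), with Sesn1 (0.49 ± 0.10) up and Trp53inp1 (-1.16 ± 0.21) down, and of 6 cell cycle genes Ccnd1 (0.81 ± 0.20) rose and Cdkn1a (-1.13 ± 0.30) fell, also when adjusted over the list alone (adjusted p = 0.238).

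Ribosomal protein and respiratory chain genes were not called as lists. Of 35 cytosolic ribosomal protein genes 6 rose, also when adjusted over the list alone (adjusted p = 0.938), led by Rpl5 (0.53 ± 0.11, SE) and Rplp0 (0.34 ± 0.08), and of 32 nuclear genes of oxidative phosphorylation 6 rose, also when adjusted over the list alone (adjusted p = 0.563), led by Ndufs1 (0.50 ± 0.12) and Sdhd (0.56 ± 0.16). With median-of-ratios scaling 1 ribosomal gene rose and 1 fell, and none of the 32 passed. Of 13 antigen presentation genes 2 rose and 1 fell (2 and none when adjusted over the list alone; 1 and 2 with either scaling; adjusted p = 0.338), with the peptide transporter Tap1 (0.61 ± 0.09) and Nlrc5 (0.29 ± 0.10) rising.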
